A study of Mus musculus with 6 samples.

How the data were processed

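Aortas of apoE knockout mice, male C57BL/6J per the labels, were taken after PBS, an empty adenovirus or an adenovirus carrying apoE. Cells positive for CD45, F4/80 and CD11b were sorted as macrophages, and cells positive for CD31 and negative for CD45 as endothelial. The labels give 6 samples, 1 for each combination of 2 cell types and 3 treatments, and the aortas of 5 mice were pooled for each sort. RNA was taken up in TRIzol, purified with an RNeasy kit and hybridized to an Affymetrix mouse gene array with whole-transcript probe sets, per the labels' protocols. Groups were taken from the sample titles.

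The values used are the deposited table of the series, 35556 probe sets on 6 arrays, which the authors had already summarised per probe set. The deposited values were taken as log2 expression because they run from 0.93 to 13.78 with array medians between 5.31 and 5.35. The log base, background correction, summary method and normalization are not given in the sources used here, so every fold change below assumes base 2. The array columns have nearly the same distribution, as values normalized across arrays do, and they are not centred per gene. A shift of total RNA between the cell types would not be visible after such a step.

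Probe sets were named through a table of platform annotation, with symbols updated by Entrez gene identifier in a RefSeq table of assembly GRCm38.p6, which served for names only. A single gene was named for 21789 probe sets, several genes for 1621, and 12146 are unnamed here. Of the single-gene probe sets, 21698 matched an identifier and 91 kept the older symbol. Values of 999 genes with several probe sets were averaged, which left 19938 genes. A background level of 4.80 log2 was set at the 95th percentile of 1194 olfactory and vomeronasal receptor genes. Genes above it on at least 1 of the arrays compared were kept, 14371 over all arrays, 13603 over the macrophage arrays and 13690 over the endothelial arrays. Where any array of a gene lies below that level, folds between cell types are given as lower bounds, with such values raised to it. Treatment differences of such genes are not exact, and counts with such values raised to background stand beside the counts of the size rule.

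The cell types were compared with limma 3.58.1 in R 4.3.3 on the log2 values, with cell type and treatment as terms, so that 2 residual degrees of freedom remained and the variance prior added 4.27. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. The same fit gave treatment tests across both cell types, apoE adenovirus against the mean of PBS and empty adenovirus, and empty adenovirus against PBS, beside PBS or empty adenovirus against the mean of the other treatments for scale. These tests are two-sided, assume the same effect in both cell types and count any difference between cell types as error. Whether both cell types of a treatment came from the same mice is not given in the sources used here, and if they did, a difference between pools, such as their sex, would count as a treatment effect. On simulated values of 14371 genes, the cell type test was run at an adjusted p under 0.05 without the 2-fold minimum. It recovered 76 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 8 false calls among 183. The full rule with the fold minimum was not simulated. The apoE test recovered 64 and 98 of 100, with 4 false calls among 166. All of these genes were changed at once and alike in both cell types, which eases the adjustment for many genes. The rates therefore do not say how often a lone change, or a change in a single cell type, would be found.

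Within a cell type each treatment has 1 array, so no error can be given there. The apoE adenovirus array was said to stand apart for a gene only where it differed at least 2-fold, in the same direction, from both the PBS and the empty adenovirus array. Before the data were examined, 38 gene lists were written, 14 of them cell type markers, with 540 genes of which 493 were measured and 47 are not analysed here. Lists with at least 4 kept genes were tested in limma with camera, at a preset correlation of 0.01 and again with an estimated correlation. Within each cell type the median of a list was set against 10000 random lists of the same size, matched on mean expression in 20 bins. Lists of genes drawn at random from simulated macrophage arrays, in which each gene varied independently, fell outside in 6.5% of cases. Percentiles describe these arrays and are not p-values.

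Genes named in the text follow a rule written before the data were examined. It takes the 12 largest differences per direction between cell types, the 3 smallest p-values per direction in each shared treatment test, the 12 per direction that stand farthest from both controls on each apoE array, the 6 per direction for empty adenovirus against PBS in each cell type, members of the lists as examples, and Apoe, Adgre1, Itgam, Ptprc and Pecam1 in any case. Unnamed or predicted genes, odorant and vomeronasal receptors, small RNAs and antigen receptor segments were left out of that ranking.

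Alternatives were quantile normalization, no filter or a filter at the median of all values, the brightest probe set per gene, an intensity trend in limma, no treatment term, no fold minimum, either control alone, unmatched random lists, and leaving out each array in turn. The cell type test without both empty adenovirus arrays, list medians for the mean of both adenovirus arrays, apoE list medians against PBS alone, and all counts and list medians with values raised to background were added after seeing the data. Further gene lists used in the closing section were also written after the main results had been seen. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.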

Results

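Gene expression was measured in macrophages and endothelial cells sorted from the aortas of apoE knockout mice, which lack apolipoprotein E and develop atherosclerotic plaques. The series title ties the apoE adenovirus to plaque regression, and the arrays address which transcripts differ in both cell types after it. There were 6 arrays, 1 each for macrophages and endothelial cells after PBS, empty adenovirus and apoE adenovirus, and each came from 5 pooled mice. Array medians lay between 5.31 and 5.35 on the log2 scale. Over all probe sets, Pearson's r was 0.978 to 0.986 between arrays of the same cell type and at least 0.894 between cell types, across probe sets, which are not independent replicates. No treatment was replicated within a cell type, so the differences between treatments within a cell type have no replicate check.

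The genes used for sorting separated the cell types on every array. Adgre1, which encodes F4/80, averaged 10.95 ± 0.18 log2 in macrophages and 3.75 ± 0.10 in endothelial cells (SD, n = 3 arrays each). Itgam, which encodes CD11b, averaged 10.47 ± 0.03 and 4.01 ± 0.46, and Ptprc, which encodes CD45, 10.84 ± 0.07 and 3.43 ± 0.29. All endothelial values of these genes were below the background level of 4.80, so macrophages exceeded them at least 71.3-fold, 51.0-fold and 66.0-fold. Pecam1, which encodes CD31, was 52.2-fold higher in endothelial cells, 12.29 ± 0.05 against 6.59 ± 0.51 (limma adjusted p = 2.85e-06). Pecam1 on the macrophage arrays was 6.11 with PBS, 7.13 with empty adenovirus and 6.52 with apoE adenovirus.

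Apoe, the gene disrupted in these mice and carried by the adenovirus, was the lowest on the apoE adenovirus array in both cell types. In macrophages it measured 8.46 with PBS, 10.10 with empty adenovirus and 7.91 with apoE adenovirus. In endothelial cells the values were 9.70, 10.17 and 7.99. Which part of the transcript the probes cover is not given in the sources used here, so these values check neither the knockout nor the virus.

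**Figure D1:**
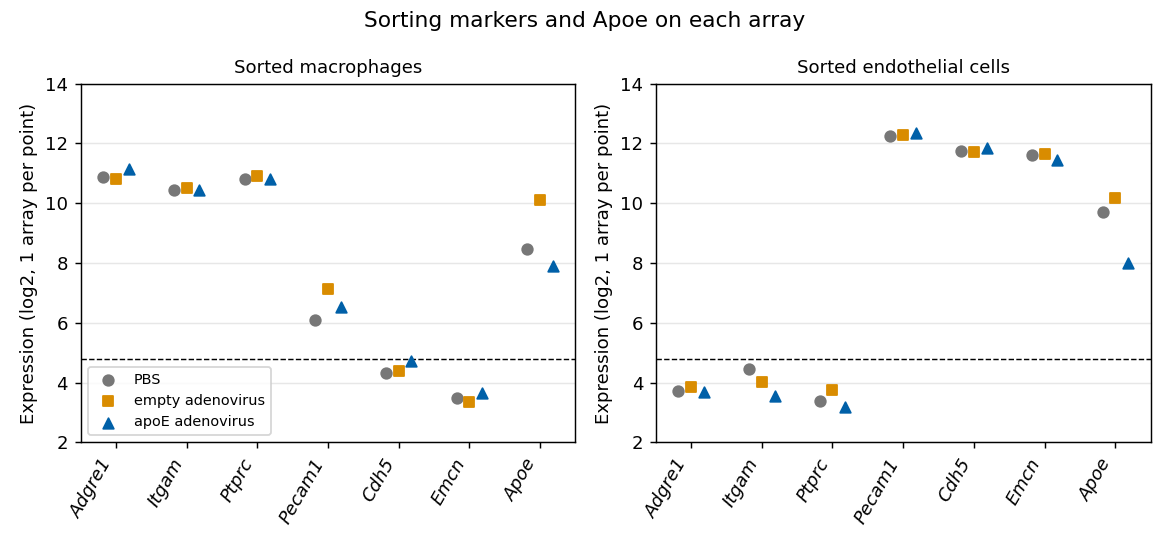
Log2 expression of the genes behind the sorting gates (Adgre1, Itgam, Ptprc, Pecam1), of Cdh5 and Emcn, and of Apoe, on the vertical axis, with 1 point for each array and the treatment as colour and shape. The dashed line is the background level of 4.80. Apoe is lowest on the apoE adenovirus arrays, 7.91 in macrophages and 7.99 in endothelial cells.

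Between the cell types, 1357 genes were higher in macrophages and 1386 higher in endothelial cells, of 14371 tested (limma, adjusted p under 0.05 and at least 2-fold, 3 arrays a side). The genes named here are the 12 largest differences in each direction before values below background are bounded, so the bounds do not keep that order. In macrophages the leukocyte receptor gene Lilr4b was at least 85.0-fold higher (7.84 ± 0.13 log2, SE, limma adjusted p = 7.82e-07). Cd52 was at least 82.2-fold higher, Wfdc17 at least 85.2-fold, Ccl8 at least 56.9-fold and Ms4a7 at least 52.2-fold. Ccl3, which encodes a monocyte-attracting chemokine, was at least 160-fold higher (adjusted p = 4.68e-05), the lysozyme gene Lyz2 at least 168-fold, the complement genes C1qa 154-fold and C1qc at least 138-fold, and the cathepsin gene Ctss at least 122-fold. In endothelial cells Emcn, encoding the sialomucin endomucin, was at least 109-fold higher (-8.07 ± 0.13 for macrophage minus endothelial, adjusted p = 7.82e-07), the phosphatase gene Ptprb at least 137-fold, the cadherin gene Cdh5 at least 126-fold, the connexin gene Gja5 at least 88.7-fold, Adgrf5 at least 86.4-fold, Cavin2 at least 82.3-fold and the angiopoietin receptor gene Tek at least 55.6-fold. Sulf1, Ldb2, Adgrl4 and Mmrn1 followed at no less than 65.9, 63.9, 60.9 and 22.0-fold. Cytl1 was 120-fold higher in endothelial cells but varied in macrophages, from 4.87 with PBS to 7.35 with empty adenovirus.

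The gene lists fixed beforehand separated in the same way. All 18 macrophage markers were higher in macrophages and all 18 endothelial markers in endothelial cells, with medians of 6.12 and -5.11 log2, and the same 18 were called in each list when p was adjusted over the list alone. Of 16 monocyte chemokines, 13 were higher in macrophages and 2 in endothelial cells. Of 16 lysosome and phagocytosis genes, 12 were higher in macrophages and 1 in endothelial cells, and of 15 alternative activation markers 11 and 0. Among 17 NF-kappaB inflammatory genes 10 were higher in macrophages and 0 lower. Of 12 LXR targets and efflux genes, which move cholesterol out of cells, 7 were higher in macrophages and 1 in endothelial cells, whereas 16 of 17 cholesterol biosynthesis genes passed in neither direction. Of 15 flow-responsive and NO-related genes 11 were higher in endothelial cells. Counts adjusted over the list alone were the same for all of these lists. Among lists of other cell types, of 9 B cell markers 7 and of 10 T and NK cell markers 8 were higher in macrophages, and of 12 fibroblast markers 7 and of 10 smooth muscle markers 6 were higher in endothelial cells. Of 36 lists tested, 23 passed camera with the preset correlation, 17 toward macrophages and 6 toward endothelial cells. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.204. Endothelial markers, all 18 of them called, had a camera p of 0.011 there, at an estimated correlation of -0.05. That version rests on the 2 residual degrees of freedom, so failing it says little about a list.

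No gene passed the test of an apoE adenovirus response shared by both cell types. Of 14371 genes, 566 had an unadjusted p under 0.05 in limma, the smallest adjusted p was 0.9996, and limma with an intensity trend also called 0 genes (smallest adjusted p 0.379, 572 at an unadjusted p under 0.05). For scale, 0 genes passed in limma with PBS (745 at an unadjusted p under 0.05) or empty adenovirus (591) set against the other treatments. The genes with the smallest p on the higher side were Zbtb16, a transcription factor gene (0.91 ± 0.12 log2, SE, 2 apoE adenovirus against 4 control arrays), the noncoding Mirt2 (0.88 ± 0.13) and Fkbp5, which encodes a chaperone of steroid receptors (0.74 ± 0.11). On the lower side they were Plac8 (-1.32 ± 0.15), Apoe (-1.66 ± 0.26) and Tmem273 (-0.88 ± 0.16). All 6 had an adjusted p of 0.9996, and Mirt2 and Tmem273 were below background on 1 endothelial array each. Zbtb16 measured 7.29, 7.22 and 8.07 in macrophages after PBS, empty and apoE adenovirus, and 8.01, 7.88 and 8.95 in endothelial cells. Fkbp5 measured 7.03, 7.10 and 7.84, and 6.85, 6.98 and 7.62.

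Among the lists, 23 cell cycle genes had a median of -0.22 log2 on the apoE adenovirus arrays relative to the controls (camera adjusted p = 9.25e-06 with the preset correlation), and no member passed alone. Neutrophil markers (-0.21), monocyte markers (-0.08), ribosomal proteins (-0.10) and oxidative phosphorylation (-0.08) also passed on the lower side, and 6 lymphatic endothelial markers (0.50) on the higher side. With an estimated correlation all 6 lists had an adjusted p of 0.895. That version passed 0 lists even between the cell types, so it does not settle whether these lists shifted. Adjusted over the list alone, Plac8 passed among the monocyte markers, Retnlg among the neutrophil markers and Mmrn1 among the lymphatic markers, against 0 genes when adjusted over all genes, and Mmrn1 was below background on all 3 macrophage arrays and Retnlg on all 3 endothelial arrays. Across 12922 genes kept in both cell types, the apoE adenovirus difference in macrophages had a Pearson's r of 0.0085 with that in endothelial cells and 49.1% had the same sign. For scale, r was -0.019 (47.0% with the same sign) with PBS set against the other treatments. With empty adenovirus set against them it was 0.045 (50.4%). Genes are not independent replicates, and no arrays are shared between these differences.

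In macrophages, 5 genes were at least 2-fold higher on the apoE adenovirus array than on both control arrays and 5 at least 2-fold lower, of 13603 kept. Those higher were the B cell chemokine gene Cxcl13 (8.73 with PBS, 9.37 with empty and 10.88 with apoE adenovirus), the acute-phase gene Saa3 (6.82, 7.17 and 8.37), Rnase2a (2.55, 3.41 and 5.22) and, outside the naming rule and chosen after their values were seen, Mir687 and the immunoglobulin gene Igha (6.67, 5.81 and 8.21). Those lower were the neutrophil collagenase gene Mmp8 (6.02, 6.03 and 4.70), Ifi214 (5.68, 5.45 and 4.36), the histone gene H2ac4 (5.73, 5.47 and 4.40) and, again outside the rule, Igkv9-120 and Gm14636. Rnase2a and Mir687 were below background on both control arrays, and Mmp8, Ifi214, H2ac4 and Igkv9-120 on the apoE adenovirus array. With such values raised to background 3 genes were higher (Cxcl13, Saa3 and Igha) and 3 lower (Mmp8, Igkv9-120 and Gm14636). For scale, the same rule gave 7 genes higher and 18 lower on the PBS array than on both other arrays. It gave 48 higher and 5 lower on the empty adenovirus array, so the apoE adenovirus array did not stand out. For the apoE adenovirus array against the empty adenovirus array alone, 14 genes were higher and 78 lower, and against PBS alone 34 and 29. Next in rank on the higher side were Rag1 (5.01, 5.99 and 6.95), the immunoglobulin chain gene Jchain (7.18, 8.02 and 8.81), Zbtb16, Fkbp5, Nuak1, Zfp846, the dim Morn2 and H2-M2, and the collagenase gene Mmp13 (7.00, 7.13 and 7.83). Next on the lower side were the chemokine receptor genes Cxcr2 (6.38, 6.37 and 5.37) and Ccr1 (7.35, 7.15 and 6.25), the heat shock gene Hspa1a (9.14, 9.22 and 8.14), the fatty acid binding protein gene Fabp5 (10.33, 10.07 and 9.16), Chil3 (7.08, 7.55 and 6.24), Cd209g, Kmo, the dim Bhlhb9 and Gbp8.

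As groups, monocyte and neutrophil genes were lower on the macrophage apoE adenovirus array. The median of 10 monocyte markers was -0.37 log2 against the mean of both controls, with 9 of 10 below 0, which is the 0th percentile of matched random lists, and it was -0.20 against PBS alone and -0.56 against empty adenovirus alone. Ccr2, the receptor by which monocytes enter tissue, measured 9.51, 9.76 and 9.06, and Plac8 7.88, 8.60 and 7.15. The 9 neutrophil markers had a median of -0.30 (percentile 0.03, and -0.46 and -0.58 against each control), chemokine receptors and egress genes -0.27 (percentile 0), heat shock genes -0.26 (percentile 0.03), cell cycle genes -0.19 with 21 of 23 below 0 (percentile 0.05), and interferon-stimulated genes -0.19 with 18 of 22 below 0 (percentile 0.01). Hypoxia and glycolysis (-0.16) and ribosomal protein genes (-0.12) were also below the central 95% of random lists, and NF-kappaB genes (0.10) and monocyte chemokines (0.09) above it. Against the empty adenovirus array alone NF-kappaB genes had 0.01 and monocyte chemokines -0.03, both within it. Cholesterol biosynthesis (-0.01), LXR targets (0.02), lipid uptake and storage (0.02), alternative activation (0.00) and macrophage markers (0.06) lay within it. T and NK cell markers (-0.17) and B cell markers (-0.31) lay below it through the empty adenovirus array, since against PBS alone their medians were 0.23 and 0.65, both above the random range. The B cell markers were split against both controls, with 4 of 9 above 0, 2 of them at least 2-fold, and a mean of 0.04. Hypoxia genes also turned to 0.10 against PBS alone, and interferon-stimulated (-0.09), chemokine receptor (-0.10) and ribosomal genes (-0.06) then lay within it. In all, 12 of 35 lists lay outside, with no replicate check. For lists of unrelated genes 1.75 are due at 5%, and 2.28 at the rate seen for random lists in simulated macrophage arrays. Members of a list can vary together, so neither number says how many are due here. For comparison, 12 lists lay outside for empty adenovirus minus PBS and 10 for empty adenovirus minus the mean of the other arrays.

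In endothelial cells, 12 genes were at least 2-fold higher on the apoE adenovirus array than on both control arrays and 14 lower, of 13690 kept. The interferon-inducible Ifi207 measured 5.37 with PBS, 6.17 with empty and 7.68 with apoE adenovirus, against 11.18 to 11.45 in macrophages, and the endothelial surface gene Cd300lg 7.23, 7.50 and 8.57. Also higher were Chad (6.70, 6.19 and 7.75), Kctd5 (5.97, 5.75 and 7.02), Ccdc85a (5.13, 5.04 and 6.13), and the dim genes Prrg3, Ibsp and Slc35f2, with Ciart, Tspan15 and Islr2 just short of 2-fold. Besides Apoe, the genes lower were Sprr1a (7.71, 8.25 and 6.10), Plac8 (7.30, 7.89 and 6.04), Apod, which encodes apolipoprotein D (7.41, 6.78 and 5.54), Macroh2a2 (5.56, 5.02 and 3.73), Mrps28 (8.25, 8.26 and 7.16), Med30, Sertad4, Arhgap20, Prokr2 and Glcci1, with Cthrc1 (7.02, 7.64 and 6.08) just short of 2-fold. Apon (3.67, 4.17 and 5.14) was below background on both controls and Tspan15 on the PBS array. With values below background raised to it, 9 genes were higher and 10 lower, of the named genes without Ibsp, Slc35f2 and Macroh2a2. Against the empty adenovirus array alone 24 genes were higher and 61 lower, and against PBS alone 101 and 63. For scale, the rule that takes both other arrays gave 10 genes higher and 36 lower on the PBS array. It gave 17 higher and 1 lower on the empty adenovirus array.

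Interferon-stimulated genes were higher as a group on the endothelial apoE adenovirus array. Their median was 0.47 log2 against the mean of both controls, with 20 of 22 above 0 (percentile 100), 0.68 against PBS alone and 0.21 against empty adenovirus alone. Irf7, a transcription factor of the interferon response, measured 6.54, 7.22 and 7.95, Ifit1 6.31, 7.33 and 7.80, and Mx2 4.98, 6.03 and 6.60. The 6 lymphatic endothelial markers had a median of 0.77 with all 6 above 0 (percentile 100, 1.11 against PBS alone and 0.50 against empty adenovirus alone). Among them were Reln (7.20, 7.91 and 8.50), Flt4 (7.99, 8.65 and 9.10), Lyve1 (9.87, 10.60 and 10.99) and Mmrn1, 0.67 log2 above the nearer control, while Prox1 measured 7.74, 7.55 and 7.64. Lyve1 was also bright on the macrophage arrays (10.85, 10.53 and 10.98). Of the macrophage genes, Lyz2 measured 4.77, 5.95 and 6.47 and Ctss 4.22, 4.68 and 5.44 on these endothelial arrays, and the macrophage marker list had a median of 0.02, within the random range. Against empty adenovirus alone that list had 0.27, above the range (percentile 99.29), and against PBS alone 0.06, within it. Antigen presentation genes had a median of 0.32 (percentile 100) that came from the PBS array, since against the empty adenovirus array alone it was -0.05. Cell cycle genes had a median of -0.25 with 18 of 23 below 0 (percentile 0.01), monocyte chemokines -0.20, oxidative phosphorylation -0.16 (-0.01 and within the range against PBS alone), apoptosis regulators 0.16 and immediate early genes 0.14, all outside the central 95%. Endothelial markers (0.03), flow-responsive genes (-0.03), leukocyte adhesion genes (-0.03), cholesterol biosynthesis (0.01) and LXR targets (-0.09) lay within it. LXR targets had -0.16 against PBS alone, below the range (percentile 1.29), and -0.15 against empty adenovirus alone, within it. In all, 8 of 35 lists lay outside. For lists of unrelated genes 1.75 are due at 5%, which does not hold where members vary together, and the simulated rate was not measured for endothelial arrays. For comparison, 9 lists lay outside for empty adenovirus minus PBS and 9 for empty adenovirus minus the mean of the other arrays.

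**Figure D2:**
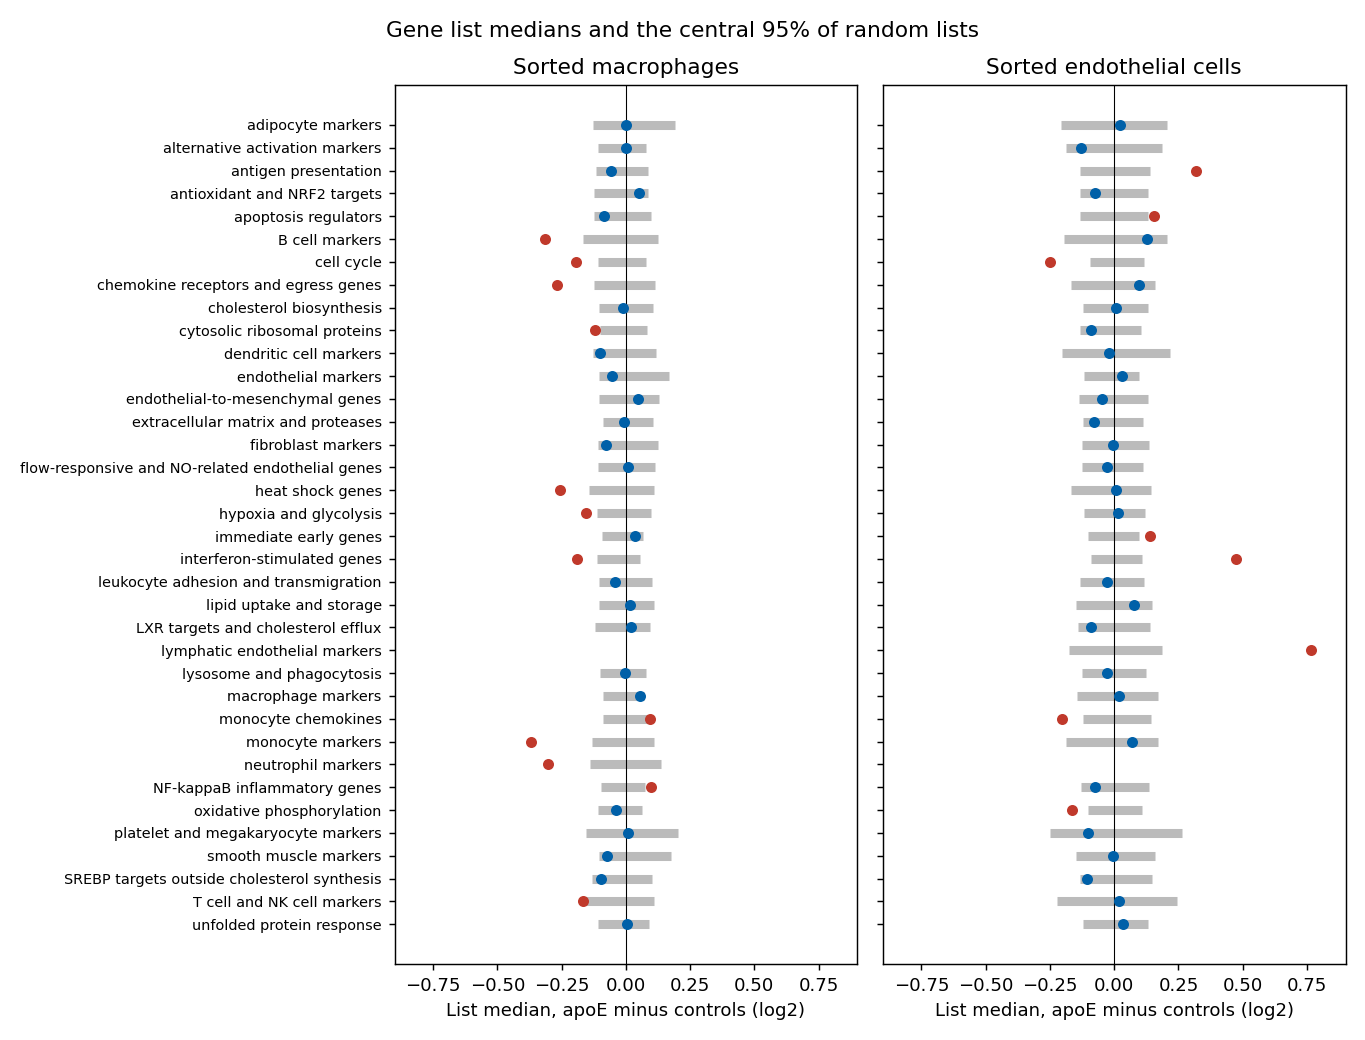
Median log2 difference of each gene list between the apoE adenovirus array and the mean of the PBS and empty adenovirus arrays, on the horizontal axis, for macrophages (left) and endothelial cells (right). Grey bars span the central 95% of 10000 random lists matched on size and expression, and points outside them are red. Interferon-stimulated genes lie at -0.19 in macrophages and 0.47 in endothelial cells.

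Empty adenovirus against PBS shows what differed without the apoE gene. No gene passed the test shared by both cell types, 692 had an unadjusted p under 0.05 in limma (smallest adjusted p 0.382), and limma with an intensity trend called 0 genes (689 at an unadjusted p under 0.05). The smallest p on the higher side belonged to the Y-linked genes Uty (1.88 ± 0.19 log2, SE, adjusted p = 0.382) and Kdm5d (1.16 ± 0.14) and to the interferon-inducible Ifi205 (1.21 ± 0.16), and on the lower side to Rasl2-9 (-1.25 ± 0.14), Nipsnap3a (-0.95 ± 0.16) and Pter (-0.76 ± 0.14). Uty, Kdm5d, Rasl2-9 and Pter were below background on at least 1 array of each cell type, Nipsnap3a on 1 endothelial array and Ifi205 on all 3 endothelial arrays, so the sizes of these shared differences are not exact. Without the endothelial empty adenovirus array 1 gene passed, Cxcl9, chosen after its value was seen. Uty measured 3.37, 5.35 and 4.19 in macrophages after PBS, empty and apoE adenovirus, and 3.68, 5.45 and 3.83 in endothelial cells. The labels give male mice for all samples, and Xist, the transcript of the inactive X chromosome, measured 9.09 to 10.34 on the 6 arrays. Of the lists, 8 passed camera on the higher side with the preset correlation, led by antigen presentation (0.46, adjusted p = 9.56e-06) and T and NK cell markers (0.53), with B cell markers, interferon-stimulated, NF-kappaB, immediate early, hypoxia and fibroblast genes. With an estimated correlation each had an adjusted p of 0.878, in a version of the test that passed 0 lists even between the cell types.

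In macrophages, 108 genes were at least 2-fold higher on the empty adenovirus array than on the PBS array and 27 lower, or 92 and 15 with values below background raised to it. The largest were Fcer2a, which encodes the low-affinity IgE receptor CD23 (below background with PBS, 7.25 with empty and 5.65 with apoE adenovirus), the interferon-gamma-induced chemokine gene Cxcl9 (6.53 with PBS, 9.73 and 7.73), the Y-linked Eif2s3y (below background with PBS, then 6.79 and 4.89), Prg4 (5.37, 7.96 and 5.63), Ctse (7.14, 9.66 and 8.75) and Cytl1. Lower were Xlr (6.34 with PBS, below background with empty adenovirus and 5.21 with apoE adenovirus), Cd209b (7.85, 6.64 and 6.98), the genes Bex1, Rasl2-9 and Defb48, which fell short of 2-fold with values raised to background, and Adck1, whose difference was -1.20 but 0.61 with its brightest probe set. B cell markers had a median of 1.32 log2 with all 9 higher and 7 at least 2-fold (percentile 100), and T and NK cell markers 0.94 with all 10 higher (percentile 100). Cd79a measured 6.86, 8.89 and 7.38, Ms4a1 6.10, 7.42 and 6.21, and Cd3g 7.06, 8.09 and 7.14. Macrophage markers had a median of -0.07 and lay within the random range. Monocyte markers (0.34), antigen presentation (0.25), immediate early (0.23), fibroblast (0.22), ribosomal (0.16), hypoxia (0.15), leukocyte adhesion (0.13) and interferon-stimulated genes (0.12) were above it, lipid uptake (-0.16) and adipocyte markers (-0.20) below it.

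In endothelial cells, 100 genes were at least 2-fold higher with empty adenovirus than with PBS and 27 lower, or 79 and 11 with values below background raised to it. Glycam1, which encodes a mucin-like ligand of L-selectin, measured 5.49 with PBS, 11.76 with empty and 10.41 with apoE adenovirus, a 77.4-fold difference between the first pair. MHC class II genes, whose products present peptides to T cells, were also higher: Cd74 measured 5.56, 8.58 and 8.54, H2-Aa 5.48, 8.38 and 7.98, and H2-Ab1 5.60, 8.22 and 7.93. Ubd measured 3.98, 6.20 and 5.78 and Stfa3 2.71, 5.93 and 2.73, both below background with PBS. Lower were Klk1b24 (6.67, 4.38 and 6.18), the chemokine gene Ccl3 (6.46, 4.29 and 3.86), the complement factor gene Cfi (7.22, 5.52 and 6.01), Mthfd2 and Mcrip2. With empty adenovirus Klk1b24, Ccl3 and Mthfd2 were below background, as was the chemokine gene Cxcl5 (5.79, 4.16 and 3.89), which fell short of 2-fold with values raised to it. The median of 12 antigen presentation genes was 0.71 with all 12 higher and 5 at least 2-fold (percentile 100), interferon-stimulated genes 0.55 and lymphatic markers 0.58 (both percentile 100). Fibroblast markers (0.31), NF-kappaB genes (0.29), lipid uptake (0.27), hypoxia (0.21) and cell cycle genes (0.19) were also above the random range, and monocyte markers (-0.16) below it. B cell markers (-0.01) and T and NK cell markers (0.16) lay within it, and Ptprc was below background on all 3 endothelial arrays. Endothelial markers lay within it at 0.03.

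**Figure D3:**
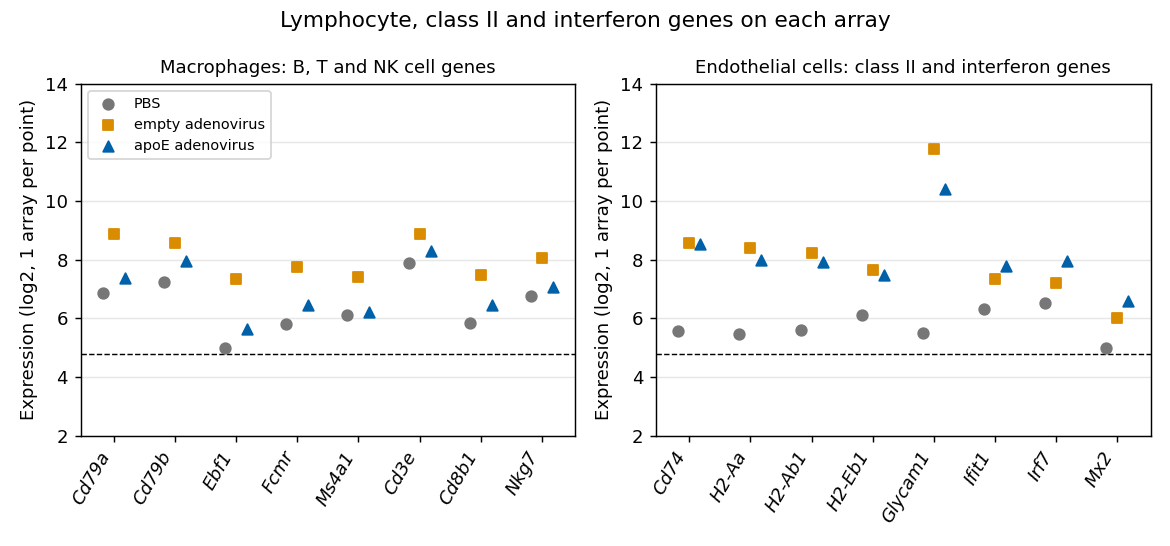
Log2 expression of B, T and NK cell genes in sorted macrophages (left) and of MHC class II genes, Glycam1 and interferon-stimulated genes in sorted endothelial cells (right), 1 point for each array, with the background level of 4.80 dashed. Cd79a is highest on the empty adenovirus macrophage array at 8.89, and Cd74 is 8.58 and 8.54 on the adenovirus endothelial arrays against 5.56 with PBS.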

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

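Of the tests in this part, only the test of further B and T cell genes was written before its result was seen. The others were chosen after the pattern, or part of the values they use, had been seen.

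The first pattern is in endothelial cells, where MHC class II genes and Glycam1 were higher on both adenovirus arrays than on the PBS array. Macrophages in the CD45- gate are argued against: Cd74 would need a macrophage share of 6.28% and 6.46%, and 12 of 12 leukocyte-wide genes stayed below the level that share brings, by a median of -2.48 log2 on the nearer array, with Ptprc at 3.74 and 3.18 and Lcp1 at 6.68 and 6.81. A larger share of capillary endothelium may contribute, since 12 capillary genes had a median of 0.64 (percentile 100 of random lists). Cd36 measured 11.04, 11.33 and 11.58 after PBS, empty and apoE adenovirus and Lpl 7.84, 8.78 and 9.21. However, all 12 are above background on the PBS array too, 3 were on a list already examined, and the CD31 gate keeps such cells. From empty to apoE adenovirus the genes of the pattern did not follow the capillary genes, of which 11 of 12 rose again. Glycam1 fell from 11.76 to 10.41, H2-Aa from 8.38 to 7.98 and H2-Ab1 from 8.22 to 7.93, and Cd74 did not rise (8.58 and 8.54). An interferon-gamma response in the adenovirus groups may also contribute. For it, 13 further genes, 1 of them on a list already examined, had a median of 0.29 (percentile 99.99). In macrophages of the same groups these genes had -0.05 (percentile 26) and interferon-stimulated genes -0.11 (percentile 2.17, mean 0.06). The macrophage arrays differed, however. Against PBS, empty adenovirus alone gave 0.11 for the further genes (percentile 95.03) and 0.12 for interferon-stimulated genes (percentile 98.97). With apoE adenovirus alone, interferon-stimulated genes had -0.09 (percentile 13.7). Both explanations stay open, because each rests on a single PBS array.

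The second pattern is in macrophages, where lymphocyte genes were higher on the empty adenovirus array. A lower macrophage share that raises every other type alike has limited evidence against it. The B cell median was 1.11 log2 above the highest of the endothelial, smooth muscle, fibroblast, adipocyte and platelet medians. That highest median, of fibroblast markers, was itself above the random range (0.22, percentile 99.63). Dim genes could hardly rise, as 13 of 18 endothelial markers were kept, and Pecam1 was 1.02 log2 higher than with PBS. The comparison therefore does not settle this point. B and T cells in the pool are a candidate source: 12 further B cell genes had a median of 0.47 and 10 further T cell genes 0.73 (both percentile 100), among them H2-Ob at 6.77 with PBS and 7.84 with empty adenovirus and Lat at 6.96 and 8.37. None of these genes was on an earlier list, all were above background on the macrophage PBS array, and the F4/80 and CD11b gate should remove B and T cells. Whether the virus or the sort brought them was not tested.

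The third pattern is Xist high and Y-linked genes low on arrays labelled male. Pools of male mice only are argued against, since the lowest Xist value was 9.09 against a background of 4.80. Pools that mix both sexes in different shares remain a candidate explanation: Kdm5d, Uty and Eif2s3y were below background on both PBS arrays and above it on both empty adenovirus arrays, where their mean was higher by at least 1.07 log2 in macrophages and 0.76 in endothelial cells, and Xist was lowest there in both cell types. The sex of the pools is therefore a possible source of differences that involve the empty adenovirus arrays, and no biological explanation was tested.

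For the 2743 genes called between macrophages and endothelial cells, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many calls, and the highest of the other splits gave 0. With 10 splits the share cannot fall under 0.05. The other splits also put both cell types on each side, so the cell type difference counted as error there. Few or no calls were due from them in advance, and the comparison adds no evidence for the calls.

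Some lists lay outside the random range in opposite directions in the cell types, and the difference was not tested. For apoE adenovirus minus controls, the macrophage median minus the endothelial median was -0.66 log2 for interferon-stimulated genes (-0.19 and 0.47) and 0.30 for monocyte chemokines (0.09 and -0.20). Against empty adenovirus alone the macrophage monocyte chemokine median was -0.03, so the opposite direction does not hold there, and against PBS alone the macrophage interferon median was -0.09, within the random range. For empty adenovirus minus PBS it was -0.43 for lipid uptake and storage (-0.16 and 0.27) and 0.50 for monocyte markers (0.34 and -0.16). No gene (0) was at least 2-fold apart from both controls in opposite directions with apoE adenovirus.

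Probe sets with no gene or several genes entered no comparison of the report. Among them, 78 of 7877 above background were at least 2-fold higher on the macrophage apoE adenovirus array than on both control arrays. Another 113 were lower by the same rule, and in endothelial cells 156 of 7809 were higher and 147 lower. The same count with PBS or empty adenovirus as the array apart was not made for these probe sets. These numbers therefore do not show whether the apoE adenovirus arrays stand out.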

How the results depend on the processing

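The cell type test without both empty adenovirus arrays the apoE list medians against PBS alone and values raised to background were chosen after seeing the data, and all other alternatives here were planned. Of the gene counts and the correlation between cell types, 87 values were unchanged and 17 were not. A gene count was unchanged within 1.5 times the reported value, the correlation within an interval around it. Of the gene list values, which are list medians and counts of lists outside the random range, 289 were unchanged. A median was unchanged if it kept its direction and its side of the range, a count if within 1.5 times. Of the medians, 19 kept only the direction and 5 reversed. Of the values of named genes, 284 kept their direction and 1 reversed. Without a fold minimum the cell type test called 2913 genes higher in macrophages and 2832 lower. Leaving out each array in turn gave 1313 to 1386 higher and 1376 to 1421 lower, and leaving out both empty adenovirus arrays 1381 and 1376. The shared empty adenovirus test called 0 to 1 genes when each array was left out, the 1 being Cxcl9 without the endothelial empty adenovirus array, where macrophages alone hold that arm and the lone array is assumed to vary like the others. The shared apoE test called 0 genes under every alternative run. With a filter at the median of all values, genes higher on the macrophage apoE adenovirus array numbered 3 and genes lower on the endothelial empty adenovirus array 14, since fewer genes were kept. With values below background raised to it, macrophages had 3 higher and 3 lower with apoE adenovirus and 15 lower with empty adenovirus, and endothelial cells 11 lower with empty adenovirus, so the rest of these calls rest on dim values. With a single control in place of both, which is a looser rule by construction, macrophages had 14 higher and 78 lower against empty adenovirus and 34 and 29 against PBS, and endothelial cells 24 and 61, and 101 and 63. Against empty adenovirus alone the apoE median reversed for antigen presentation in endothelial cells (-0.055) and for monocyte chemokines in macrophages (-0.032), and against PBS alone for B cell markers (0.648), T and NK cell markers (0.228) and hypoxia genes (0.103) in macrophages. The Adck1 difference in macrophages became 0.607 with its brightest probe set, and the cause was not tested. Signal over background limits the dim genes: 5567 of 19938 genes were below background on all arrays. No paired analysis was possible by replicate number because the labels give none, and the cell type fit already pairs the arrays by treatment.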

Other observations

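The glucocorticoid test below was written before the values of its genes were seen. Fkbp5 and Zbtb16, the genes on the higher side of the shared apoE test with named proteins, are both known to be induced by glucocorticoids. A hypothesis is that glucocorticoid exposure differed between the pools, as it may with handling or sampling. Further glucocorticoid-induced genes, 10 in macrophages and 9 in endothelial cells, had medians of 0.12 and 0.47 log2 on the apoE adenovirus arrays against the mean of both controls, at percentiles 97.62 and 100 of matched random lists. Of these genes, 7 of 10 in macrophages and 9 of 9 in endothelial cells were above the mean of the controls, and 6 and 7 were above both controls. The macrophage value lies at the edge of the central 95%, whose upper end is 0.117. Klf9 measured 6.39, 6.37 and 6.84 in macrophages after PBS, empty and apoE adenovirus and 7.34, 7.40 and 7.84 in endothelial cells, and Mt1 10.52, 10.41 and 10.86, and 8.96, 9.54 and 9.80, whereas Il1r2 measured 7.57, 8.25 and 7.58 in macrophages and Cebpd 7.33, 8.19 and 7.90 in endothelial cells. The result is in line with the hypothesis, rests on 1 array per cell type, and does not separate exposure from an effect of apoE.

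Capillary genes, examined after the main results, were higher with empty adenovirus than with PBS and higher again with apoE adenovirus in endothelial cells for 11 of 12 members. Timp4 measured 6.87 with PBS, 7.72 with empty and 8.10 with apoE adenovirus, Mgll 9.08, 9.75 and 10.02, and Car4 7.24, 7.92 and 8.37, whereas Meox2 measured 8.63, 8.78 and 8.55.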
